A study of Mus musculus with 2 samples.

How the data were processed

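CTCF, a zinc-finger protein that binds DNA at insulators and at the anchors of chromatin loops, was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in pro-B cells. Per the labels' protocols, CD19-positive cells were enriched with magnetic beads from bone marrow of Rag1-deficient C57BL/6 mice aged 5 to 8 weeks. Rag1 encodes a subunit of the recombinase that assembles antigen receptor genes, so B-cell development in these mice stops at the pro-B stage. Per the labels' protocols, chromatin was crosslinked with 1% formaldehyde for 10 minutes and precipitated with an antibody against CTCF, and gel-selected libraries of about 200 to 250 bases were amplified for 15 PCR cycles and sequenced on an Illumina instrument. The labels list 1 CTCF ChIP library and 1 input library, and a processed file of the ChIP library was analysed here. Values of the input library were not analysed here.

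Per the submitters' processing notes, Bowtie and the mouse build mm9 were used. The Bowtie version, the peak caller, its threshold and the way the input entered the calls are not given in the sources used here. The deposited file is a browser track of genomic coordinates in bases, the only values that the authors gave. It holds 691171 bins with 3 fields each (chromosome, start and end), and every bin is 25 bases long. None of the bins overlap, and the bins of each chromosome lie on one grid. The file gives no height, score, read count or p-value, so the sequencing depth is unknown, and the strength of binding at a site was not measured. On 10 of the 21 chromosomes the last bin ends past the last gene of the GRCm38 gene table. The table gives no chromosome lengths, so this does not decide the build, which is taken from the submitters' processing notes. Coordinates are printed in mm9, counted from 1, with the deposited starts read as BED starts.

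Runs of adjacent bins were taken as CTCF regions. Before the data were examined, such runs were planned for a signal track, with a floor on its values. Because the bins carry no values, every run was taken. The plan ranked peaks by height. Because the file holds none, region width took its place in the rule for the named items: the 10 widest regions of the genome stand where the 10 highest peaks were planned. For spacing, windows and chains, regions within 500 bases of each other were joined first, because many narrow runs lie beside another run. This step, and the measures of spacing, of windows and of chains, were chosen after the data were seen.

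Density per chromosome was the number of regions divided by the end coordinate of the last bin. Exact Poisson 95% intervals cover counting error only and are too narrow where neighbouring regions are not independent. The ratio of the X to the autosomes therefore has a 95% interval from 10000 resamplings of 5-Mb blocks. The 95% interval of the X median width came from 2000 resamplings of widths, not of blocks. It may likewise be too narrow. Protein-coding genes per chromosome were counted in the NCBI RefSeq gene table of GRCm38, which served for the number of genes on each chromosome and, apart from the check of the build above, for no coordinates. Random placement was described with 100 sets in which the joined regions of each chromosome, with their widths, were placed uniformly between its first and last region, and with 100 further sets in which each region was placed within its own 1-Mb window. Placed regions within 500 bases were joined as the observed ones were, so the sets hold somewhat fewer regions than the file. Chains were runs of joined regions with gaps of at most 5 kb. With 1 library and no replicate, no test between samples was possible and no p-value is given. Sets placed at random describe this library only.

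The scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated bins: all 40682 simulated regions were recovered, an X simulated at 0.4 of the autosome density came out at 0.407, spacings of 20 to 200 kb of uniformly placed regions came out at 1.02 times the random expectation, and a simulated chain of 12 regions was found with 12 members. The simulated regions were kept apart from each other, and the frequency of spacings under 20 kb was not checked. Alternatives were thresholds on width, joining of neighbours, removal of single bins, other chromosome lengths, gene numbers in place of length, bases in place of regions, and other chain gaps. The planned parts that need an annotation or a sequence of mm9 were not analysed here: annotation classes, the CTCF motif, the antigen receptor loci, V segments, gene lists and gene clusters. For the same reason regions are given by position and none is assigned to a gene.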

Results

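CTCF binding was profiled in 1 ChIP-seq library of Rag1-deficient mouse pro-B cells, in a series on CTCF sites in lymphocyte subsets. There was no replicate, and the depth of the library is unknown because the file gives positions only. The comparisons that such a list allows are between parts of one genome. They cover how many regions were listed, how these were spread over the chromosomes and spaced, and where they were widest or most crowded. The values below describe this library, and no background could be set beside them because the input library was not analysed here.

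In these pro-B cells 41576 runs of adjacent bins were taken as CTCF regions, and together they covered 17.3 Mb. The median region was 500 bases wide, with quartiles of 225 and 600 bases. The most frequent width was 600 bases, held by 3805 regions. Of all regions, 20944 (50.4%) were 450 to 650 bases wide. Only 270 regions exceeded 1000 bases, and the 99th percentile of width was 925 bases.

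A second, smaller group of regions was narrow. Of all regions, 10370 (24.9%) were at most 200 bases wide, and 2602 consisted of a single 25-base bin. Of these single bins, 1521 (58.5%) lay within 100 bases of another region, whereas 490 of the 20089 regions over 450 and up to 650 bases wide (2.44%) did so. When regions within 500 bases were joined, 37379 regions with a median width of 525 bases were left, of which 6182 (16.5%) were at most 200 bases wide. A separate rise stood at 325 bases, a width held by 2054 regions against 780 at 25 bases less and 1066 at 25 bases more.

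**Figure D1:**
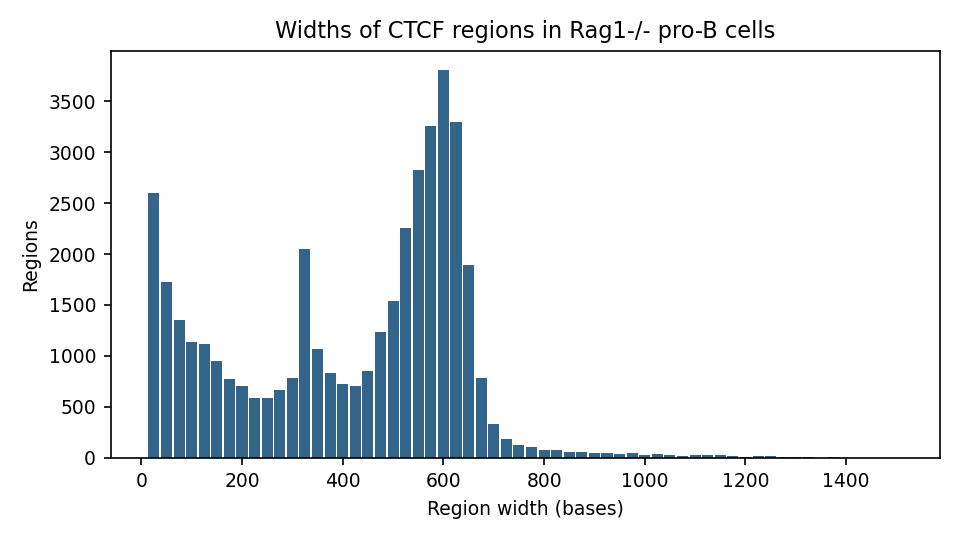
Number of CTCF regions (vertical axis) at each width in bases up to 1500 (horizontal axis, steps of 25 bases) in the single CTCF ChIP library. The tallest bar of the main class stands at 600 bases with 3805 regions, a second rise at 325 bases holds 2054, and single bins number 2602.

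The number of CTCF regions per Mb differed between chromosomes. The 19 autosomes carried 16.6 ± 3.84 regions per Mb (mean and SD over chromosomes). Chromosome 11 was the densest at 27.3 regions per Mb (95% Poisson interval 26.4 to 28.2), followed by chromosome 19 at 22 and chromosome 17 at 20.1. Chromosome 3 was the sparsest autosome at 12 regions per Mb (11.4 to 12.5), and chromosome 18 had 12.5. Chromosome 12, which carries the immunoglobulin heavy chain locus, had 13.6 regions per Mb. Chromosome 6, which carries the immunoglobulin kappa light chain and T-cell receptor beta loci, had 15.3. Both values average whole chromosomes and do not describe these loci.

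Region density followed the density of protein-coding genes across the autosomes. Over the 19 autosomes Pearson's r was 0.89 and Spearman's rho 0.91. Without chromosomes 7 and 11, the 2 farthest from the median gene density, r was 0.94 over 17 autosomes. Chromosomes of one library are not replicates, so no p-value is given. Counted per gene, chromosome 11 was no longer apart, with 207 regions per 100 protein-coding genes against 196 for all autosomes and 194 for chromosome 3. Chromosome 7 stood below the others with 138 regions per 100 protein-coding genes, and the remaining autosomes ranged from 181 to 243, the latter on chromosome 12.

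The X chromosome was the sparsest of the chromosomes other than the Y. It held 1009 regions, or 6.06 per Mb (95% Poisson interval 5.69 to 6.45), which was 0.369 of the pooled autosome density (95% interval 0.262 to 0.483 from resampled 5-Mb blocks). Per 100 protein-coding genes it held 104 regions, 0.532 of the autosome value. Regions on the X were also narrower, with a median of 375 bases (95% interval 350 to 400) against autosome medians between 475 and 500 bases. The shortfall was deepest among regions over 550 bases and showed no trend with width below that. Among regions of at most 200 bases the X had 0.445 of the autosome density (95% Poisson interval 0.396 to 0.498), among those over 200 and up to 450 bases 0.512 (0.455 to 0.573), and among those over 450 and up to 550 bases 0.446 (0.390 to 0.508). The ratio was 0.205 (0.175 to 0.239) for regions over 550 and up to 650 bases and 0.106 (0.0604 to 0.172, 16 regions on the X) for those over 650 bases. The Y chromosome held 1 region, a single bin.

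**Figure D2:**
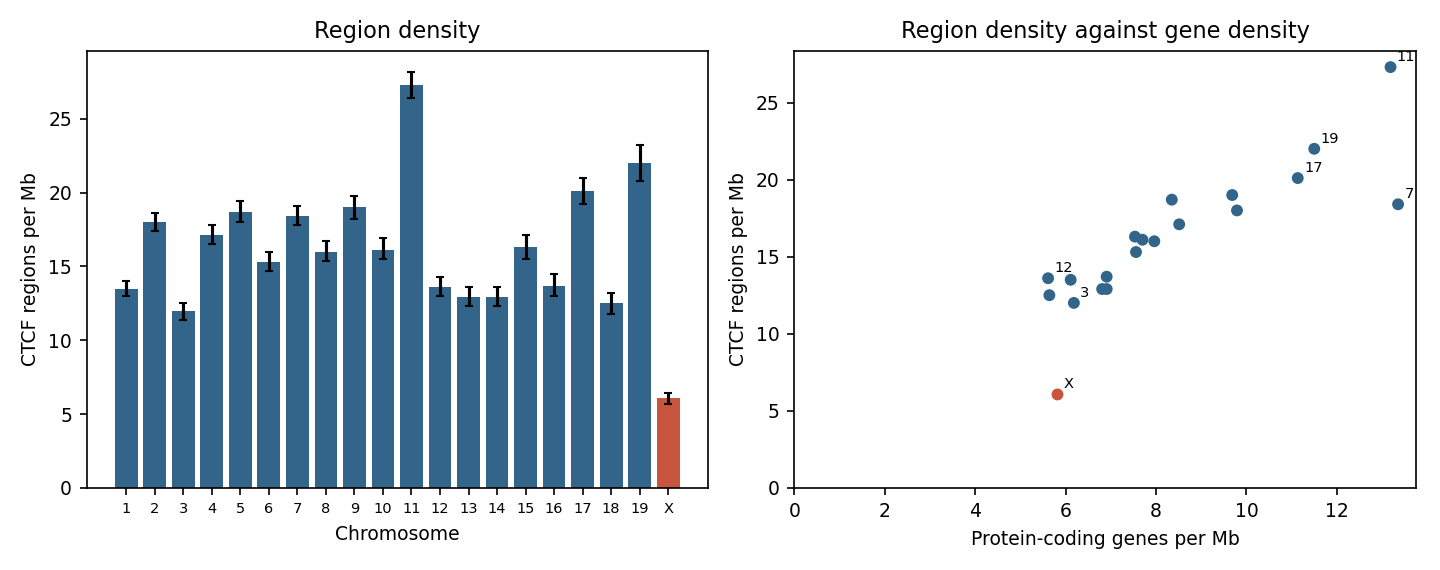
Left, CTCF regions per Mb (vertical axis) on each autosome (blue) and the X (red), with bars from 0 and exact Poisson 95% intervals. Right, the same densities against protein-coding genes per Mb, 1 point per chromosome (some named); the X lies at 6.06 regions per Mb, below all autosomes, and chromosome 11 at 27.3 is the highest.

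Along the autosomes, regions were denser toward the distal end. Mouse chromosomes have their centromere at the start of the coordinates. Each autosome was divided into 10 parts of equal length. The last part had 1.49 ± 0.57 times the chromosome's mean density (mean and SD over 19 autosomes) and was above the mean on 15 of 19 autosomes. The part before it had 1.22 ± 0.55 and was above the mean on 13 of 19. The first part had 0.55 ± 0.29 and was above the mean on 1 of 19. Measured from the first bin of each chromosome, which leaves out the stretch with no bins at its start, the first part had 0.77 ± 0.43 and the last 1.46 ± 0.56.

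CTCF regions were crowded into part of the genome. In 2399 windows of 1 Mb on the autosomes the median was 11 joined regions, with quartiles of 4 and 22. The variance over the mean was 13.7, against 1.52 to 1.67 in 100 sets placed uniformly along each chromosome. The densest 10% of the windows held 30.7% of the regions. This share was not computed for the uniform sets, where windows picked as the densest would also hold more than 10%. No joined region fell in 268 windows, against at most 2 in any uniform set. Neighbouring windows resembled each other, with a correlation of 0.62 against 0.35 to 0.42 in the uniform sets.

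The densest windows lay side by side on chromosome 10, from 80000001 to 81000000 with 89 joined regions and from 79000001 to 80000000 with 83. They were followed by chromosome 7 from 52000001 to 53000000 with 78. On chromosome 17 the adjacent windows from 34000001 and from 35000001 held 70 and 77 regions. The most crowded window of any uniform set held 46.

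**Figure D3:**
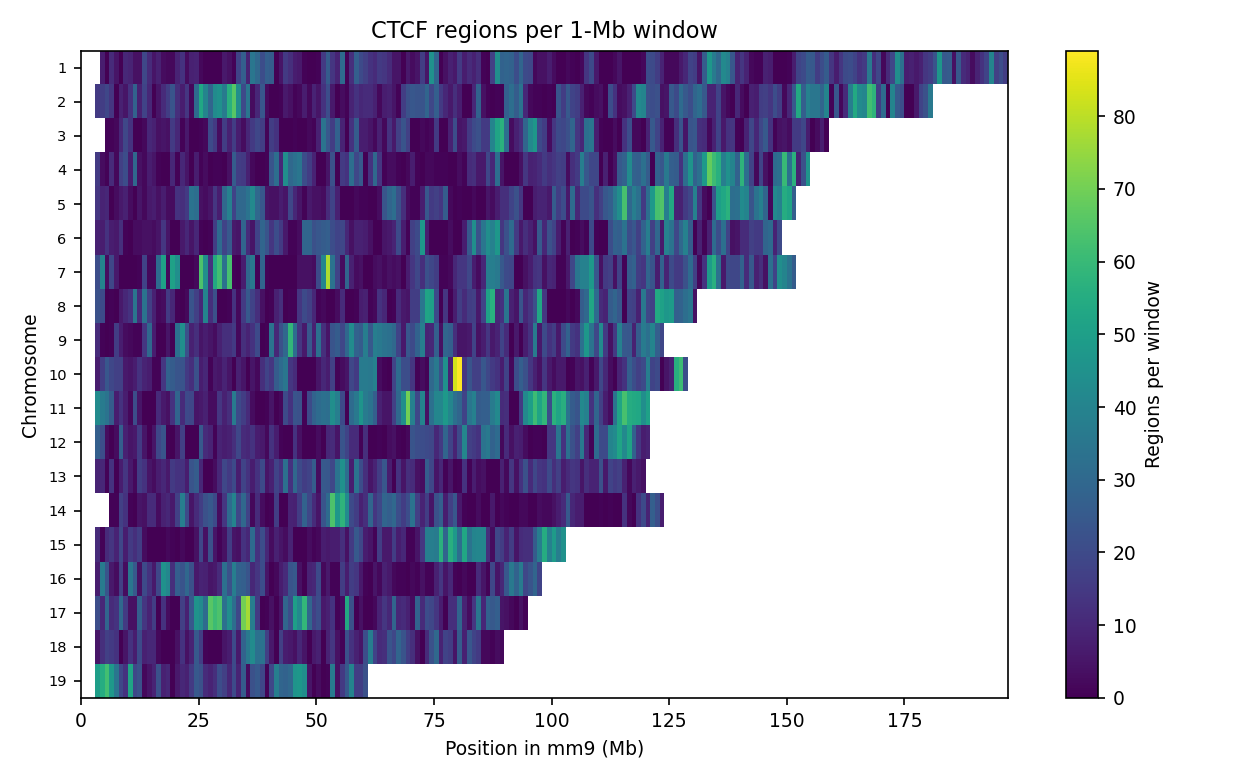
Joined CTCF regions per 1-Mb window (colour scale) along the 19 autosomes (rows) by position in mm9 (horizontal axis, Mb). Bright windows cluster, with the maximum of 89 regions on chromosome 10, and 268 windows hold none.

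Neighbouring regions also lay closer together than random placement gave. The median spacing between midpoints of joined regions was 20.9 kb, against 45.6 to 47.1 kb in the 100 uniform sets and 29.3 to 30.2 kb in the 100 sets placed within 1-Mb windows. Of all neighbouring pairs, 6585 (17.6%) were within 5 kb, which was 2.96 times the uniform mean and 1.78 times the mean of the sets placed within 1-Mb windows. The excess over the latter sets was 2.10-fold for spacings of 1 to 2 kb and 1.28-fold for 5 to 10 kb. Spacings of 50 to 100 kb were scarcer than in the same sets, at 0.777 of their mean.

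Long stretches were free of CTCF regions. There were 300 gaps over 1 Mb, against at most 9 in any uniform set and 215 to 242 in the sets placed within 1-Mb windows. The X held 29 of them and 5 of the 10 longest, and such gaps took up 48.7% of the X and 21.9% of the autosomes. The longest ran on the X from 23143186 to 33223260 (10.1 Mb). The X gaps from 111672061 to 119279060 (7.61 Mb) and from 119279111 to 125838385 (6.56 Mb) were parted by a single narrow region. Without that region they would form 1 stretch longer than 10.1 Mb. The longest gap on an autosome ran on chromosome 7 from 39052480 to 46739704 (7.69 Mb). Whether these stretches hold assembly gaps or repeats was not analysed here.

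**Figure D4:**
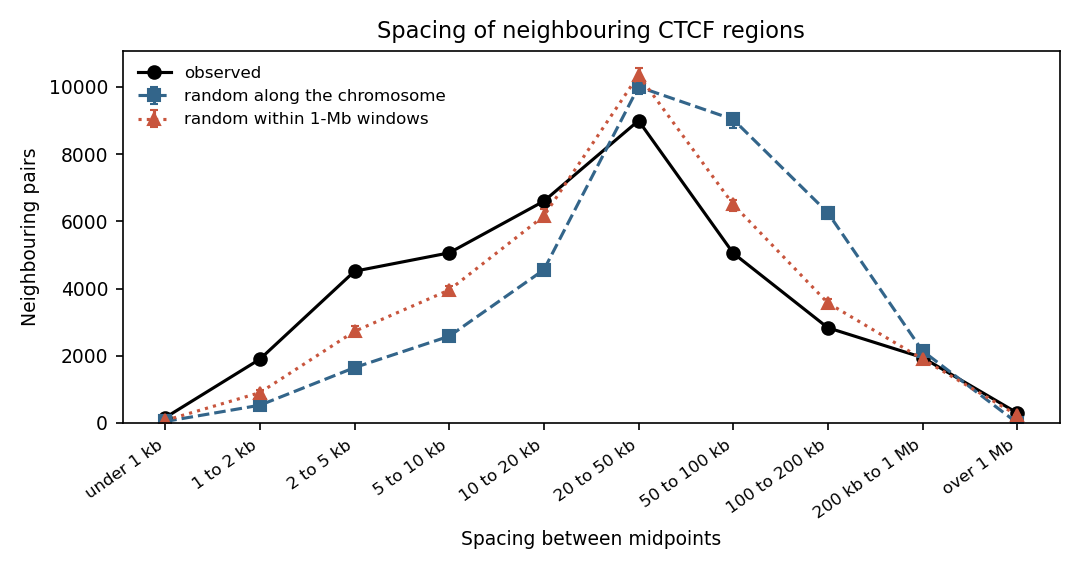
Number of neighbouring pairs of joined regions (vertical axis) by the spacing of their midpoints (horizontal axis). Black points are observed, blue squares the mean of 100 sets placed along the chromosome and red triangles the mean of 100 sets placed within 1-Mb windows, with bars from the lowest to the highest set; observed pairs exceed both at 1 to 2 kb (1899 pairs) and fall below both at 50 to 100 kb (5052 pairs).

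The widest region of the genome lay on chromosome 17 from 39979752 to 39985951. It was 6200 bases wide, with none of its 248 bins missing, and its nearest neighbour was 352975 bases away. The next widest, 2025 bases, lay on chromosome 12 from 114457911 to 114459935. This region was the centre of a group: within 10 kb of its edges lay 5 regions, itself included, from 114454011 to 114462910, with widths of 600, 1325, 2025, 1375 and 650 bases. Together they covered 5975 bases. The third widest region, 1725 bases, lay on chromosome 2 from 147003274 to 147004998, and the fourth, 1675 bases, on the same chromosome from 152656124 to 152657798. The remaining 6 of the 10 widest measured 1500 to 1675 bases and lay on chromosomes 5, 7, 8, 10 and 11.

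By the share of sequence covered in 10-kb windows, the same places on chromosomes 17 and 12 led the list. The window on chromosome 17 from 39980001 to 39990000 was covered to 59.5%, and that on chromosome 12 from 114450001 to 114460000 to 39.5%. With windows shifted by 5 kb, the chromosome 12 window from 114455001 to 114465000 came first at 53.8% and the chromosome 17 window second at 52.5%. The third window reached 32.8% in the first grid and 32.0% in the shifted one.

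The longest chain of neighbouring regions lay on the X. Of the joined regions, 24607 had no neighbour within 5 kb, and the others formed 5521 chains of 2 or more. Only 81 chains had 5 or more members, 2 of them on the X. The longest had 14 members and ran over 32.9 kb from 47943761 to 47976610, with a median member width of 462 bases and a median gap of 1800 bases. The next longest were 2 chains of 8 members, both on chromosome 10, from 74383503 to 74403827 and from 79230978 to 79256552. In 100 sets placed at random within 1-Mb windows the longest chain was 11 members in the genome and 5 on the X. The chains of 8 members were thus within what random placement at the local density gave. The rank of the X chain depended on the counting. With gaps up to 10 kb the longest chain again lay on the X, with 21 members. When regions within 2 kb were joined first, the longest had 7 members and lay on chromosome 10. Among regions at or above the median width, it had 6 members and lay on chromosome 1. The last 2 settings take members out of the X chain by construction. Its median gap was under 2 kb and its median member width was under the width limit.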

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

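No paired analysis was possible because the design has 1 ChIP library and no replicate. With 1 library no replicate could be left out. Joining regions within 500 bases was planned for the number and width of regions, and counting per gene for the density by chromosome. All other alternatives were chosen after the data were seen, among them joining for any other result and the width thresholds, which replaced the planned thresholds on height. The number of regions fell from 41576 to 21119 at or above the median width and to 11252 at or above the upper quartile of 600 bases, ties included, by the construction of these limits. It was 37379 after joining within 500 bases and 38974 without single bins. The X to autosome ratio of 0.369 became 0.532 when the expectation came from protein-coding genes, and it stayed below 1 in all 6 alternatives tried, from 0.273 to 0.532. The ratio of chromosome 11 to the autosomes fell from 1.66 to 1.05 and that of chromosome 3 rose from 0.729 to 0.989 when genes replaced length. The longest chain had 21 members with gaps up to 10 kb, 7 when regions within 2 kb were joined first and 6 among regions at or above the median width. The excess of neighbours within 5 kb over placement within 1-Mb windows ranged from 1.78 to 2.03. Depth is unknown, so whether an absent region was unbound or missed could not be told from the file. The planned parts on annotation classes, the motif, antigen receptor loci, V segments, gene lists and gene clusters were not run, because they need an annotation or sequence of mm9.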

Other observations

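Of the tests below, 2 were written before their result was seen: joining the regions of the X, and random placement of the X chain. The test of the widest region was chosen after its result was seen. It restates the observed width, so it cannot tell causes apart.

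Chromosome 12 carried the most regions per protein-coding gene, 243 per 100, and also the group around the second widest region. Per Mb, however, it had 13.6 regions against an autosome mean of 16.6. Only genes of the protein-coding class, 679 on this chromosome, were counted. The immunoglobulin heavy chain locus lies toward the distal end of chromosome 12 and is known to be flanked by an array of CTCF sites. Whether the group from 114454011 to 114462910 belongs to that locus was not tested, since no mm9 annotation was used here. Other crowded places were a chain of 7 regions on chromosome 1 from 88416871 to 88436595, another of 7 on chromosome 12 from 81242336 to 81263760 and one more of 7 on chromosome 19 from 4037761 to 4052485. None of these chains was longer than random placement at the local density gave, with up to 11 members in the genome.

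The X had fewer regions per Mb than any autosome, 0.369 of the autosome density, and its regions were narrower, with a median of 375 bases against 475 to 500. Splitting of regions by unmapped repeats would raise the number of regions, so it bears only on their narrowness. After joining within 500 bases the X median was 450, with an upper bound of 475. This was still below the lowest autosome median of 500, although the X median rose from 375 and the lowest autosome median from 475. Joining cannot restore pieces split by longer repeats or lost at an edge, so splitting is not excluded. The density ratio after joining was 0.368. Fewer sites on the X, and less signal per site as 1 bound copy per cell would give, both stay open, because the file gives no binding strength and width was not shown to measure it. The sex of the mice, the input and the mappability of the X were not analysed here, and the design has no group that tests a biological cause.

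The longest chain of regions lay on the X, which had fewer regions per Mb than any autosome. Random placement at the local density gave at most 5 members on the X in 100 sets, against 14, and at most 11 in the whole genome. A tandem array of CTCF sites is a hypothesis that stays open, as do 1 broad region broken up by the threshold and a repeated sequence that shares reads among its copies. The X is known to carry loci with tandem CTCF sites, such as Firre and Dxz4, and the chain was not assigned to either.

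Before joining, the widest region, on chromosome 17, was 3.06 times as wide as the next. That next region, on chromosome 12, lay 150 bases from a region of 1375 bases, so joining within 500 bases would lessen the ratio. The chromosome 17 region was unbroken and alone. A sequence present in many copies in the genome and once in the assembly could give such a block, as could broad binding, and they cannot be told apart because neither the input nor the mm9 sequence was used here. The rise at 325 bases in the widths, 2054 regions, has no tested cause.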
